A study of Danio rerio with 6 samples.

How the data were processed

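RNA was measured in whole embryos of 3 wild-type and 3 csf1ra mutant samples at 3 days post fertilisation, from 30 embryos per genotype or per sample (the labels can be read either way), with 1 μg of total RNA per library. Per the submitters' processing notes, which give no roles or order, the tools were Trimmomatic 0.30, HISAT2 2.0.1, HTSeq 0.6.1, DESeq, Cufflinks 2.2.1 and SAMtools 0.1.18, with the genome build GRCz10. The settings of these tools and the read depth are not given in the sources used here.

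The values in each library's table are FPKM, per the file headers, for transcript-structure events such as alternative first exons, last exons, skipped exons and retained introns. The authors gave 60204 to 61834 events of 20 types per library, and events at 0 are not listed. A gene's value can thus be missing because its transcripts were assigned to another structure in that library. A second table, for the whole series, holds the authors' own test of each transcript. The p-value and adjusted p-value in it are the authors' own, per the file headers, and its smallest p-value is 5e-05. It also holds 2 columns of values, 1 for each side of the comparison. Their names do not say which side is which genotype, so these 2 columns and the fold column were not used here, and the comparison of directions planned with that table was not made. Gene names came from the deposited table, which paired 19363 of the 19364 listed gene IDs with a symbol.

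A gene's total per library was the larger of the summed FPKM of its first-exon events and of its last-exon events. Both sums were equal within 1% for 68.5% of genes. Genes with neither kind of event have no total, among them 2038 of the 18800 genes tested in the authors' deposited table. A gene was counted as significant in that table where at least 1 of its tested transcripts had an adjusted p under 0.05.

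Read counts were not used here, so count models and library-total scaling were not run. The design written before the data were examined named limma as the test for FPKM: limma 3.58.1 in R 4.3.3, with trend and robust options, on log2(FPKM + 1) over genes with at least 1 FPKM in at least 3 libraries, genotype as the only term, a two-sided test, Benjamini-Hochberg adjustment over 15476 genes and a threshold of 0.05. Of these genes, 15016 were listed in all 6 libraries. A gene not listed in a library entered the tests as 0 FPKM. The fold changes and SEs of such genes depend on that 0 and on the 1 added to each value. csf1ra itself was kept out of the list tests. The 47 gene lists were fixed before the data were examined, and 43 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. An enrichment test of annotation terms was planned and could not be run, because the files carry no such terms. Splits of the libraries and the exact permutation test of csf1ra were computed in R. Gene positions and Fisher exact tests were computed with Python, pandas and SciPy.

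Genes were named by a rule set before the data were examined. It took csf1ra, csf1rb, csf1a, csf1b and il34; the 12 largest positive and 12 largest negative log2 fold changes among called genes whose genotypes did not overlap, with at least 5 FPKM in the higher genotype and a gene-name symbol; up to 4 members of smallest p in each list discussed; and called genes near csf1ra, taken here as those within 10 Mb that all 6 libraries listed. Genes outside the rule were chosen after their values were seen: slc2a15b, mpeg1.1, lgals9l1, mafba, prss59.1, cpb1, sycn.2 and the genes of the closing section.

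The procedure was tested on simulated log2 values for 15476 genes with the real means and spreads and 200 changed genes. For the comparison of mutant and wild type it called 75% of the genes changed 2-fold and 97% of those changed 4-fold, with 12 false calls. Of 40 unchanged lists it called 0. Changed genes were drawn only from those with a mean of at least 5 FPKM on the log2 scale, so lower genes were not tried. Noise was drawn for each gene alone, and missing listings were not simulated. The 0 of 40 thus does not bear on real lists, whose members can vary together. The precision that depth allows cannot be stated without read totals, so the spread between libraries is the only error given.

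The alternatives tried were quantile normalisation, median-ratio rescaling, no filter and a filter of 5 FPKM, limma without trend and robust options, pseudocounts of 0.1 and 0.5, the replicate number as a block, leaving out each library, a minimum log2 change of 1, and an estimated correlation for lists. Chosen after seeing the data were first-exon events alone, last-exon events alone, genes listed in all 6 libraries alone, and limma on list means.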

Results

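The data are RNA-seq measurements of whole zebrafish embryos at 3 days post fertilisation, from wild-type fish and from fish homozygous for a csf1ra mutation made with CRISPR/Cas9. csf1ra encodes a receptor for colony-stimulating factor 1 that acts in macrophages, microglia and the yellow pigment cells called xanthophores. Each genotype had 3 libraries. The labels do not state whether these came from separate clutches, so the p-values measure the spread between these samples, which may be partly technical. Per library, 17291 to 17653 genes were listed with a value in FPKM, and the 10 most abundant genes held 8.97% to 10.8% of the summed FPKM. The files give no read totals, so the depth behind each value is unknown. Values are given as the mean FPKM ± SD with n = 3 libraries per genotype, and fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

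The targeted gene was measured first. csf1ra (ENSDARG00000102986; GRCz10 chromosome 14, 3170816 to 3202038, minus strand) stood at 4.54, 4.07 and 3.72 FPKM in the wild-type libraries. Of the mutant libraries, replicates 1 and 2 did not list it, and replicate 3 held 0.563 FPKM. Its log2 fold change was -2.14 (SE 0.22, limma adjusted p = 0.00282), with the missing listings entered as 0. With a pseudocount of 0.1 in place of 1 it was -4.48 (limma adjusted p = 0.042). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 allows. The authors' deposited table gave its adjusted p as 0.000466. The paralogue csf1rb was at 6.80 ± 0.79 FPKM in wild type and 3.68 ± 1.05 in the mutant (log2 fold change -0.75, adjusted p = 0.0791). The ligand genes csf1a (2.28 ± 0.58 and 1.67 ± 0.28 FPKM), csf1b (2.64 ± 0.47 and 2.84 ± 0.44) and il34 (1.17 ± 0.035 and 1.38 ± 0.047) did not pass the test, with adjusted p of 0.48, 0.852 and 0.721. In the authors' deposited table csf1a was significant (adjusted p = 0.00905), and csf1b and il34 were not (0.888 and 0.985).

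Between the genotypes, 6 of 15 tested genes of yellow pigment cells and pteridine synthesis and 3 of 17 of macrophages and microglia fell in the mutant, and 5 of 10 genes of the exocrine pancreas, which makes digestive enzymes, rose. The lists' own calls were lost with an estimated correlation (camera adjusted p = 0.27, 0.276 and 0.72). The correlation estimated among the members was 0.052, -0.016 and 0.84, against the preset 0.01. That of the macrophage list lay below the preset, so more correlation among its members does not account for its loss. Among the genes named for their fold, the greatest fall on the log2(FPKM + 1) scale was that of s100v2, a calcium-binding S100 family gene. It stood at 40.3 ± 1.8 FPKM in wild type, against 0.370 and 0.191 FPKM in mutant replicates 2 and 3. Mutant replicate 1 did not list it (log2 fold change -5.13, SE 0.13). Its value rests on last-exon events. slc22a7a, a member of the organic anion transporter family, fell from 14.6 ± 1.8 to 2.0 ± 0.77 FPKM (-2.41, SE 0.19). ms4a17a.8, a gene of the membrane-spanning MS4A family, was not listed in any wild-type library and stood at 7.28 ± 0.30 FPKM in the mutant, also from last-exon events. In all, limma called 376 of 15476 genes at an adjusted p under 0.05, of which 190 were higher and 186 lower in the mutant. Of these, 159 changed by at least 1 on the log2 scale. The count was 147, 139 and 156 without wild-type replicates 1, 2 and 3, and 147, 135 and 450 without mutant replicates 1, 2 and 3.

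The libraries separated by genotype along the first principal component, which held 40.6% of the variance. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.969 to 0.977 within a genotype and 0.955 to 0.960 between genotypes. The second component, with 18.3%, set mutant replicate 3 apart, at -30.5 against -2.17 to 14.5 in the other libraries. In 3446 genes (22.3%) the genotypes' values did not overlap, where chance gives 10%.

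**Figure D1:**
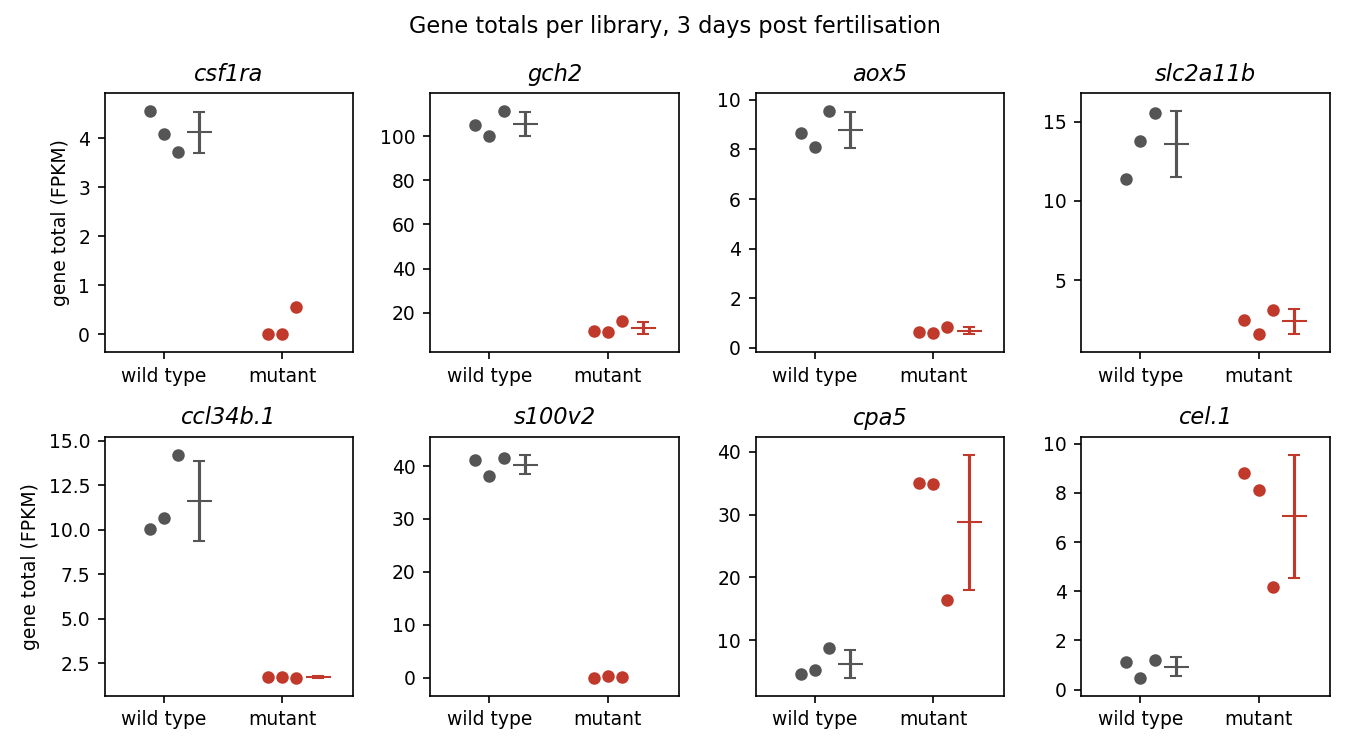
Gene totals in FPKM (vertical axes, linear, one scale per gene) of 8 genes in each wild-type and mutant library, with points for libraries and a bar with whiskers for the mean ± SD of 3 libraries (libraries that do not list a gene are drawn at 0, without a mean). gch2 lies at 105 ± 5.6 FPKM in wild type and 13.2 ± 2.9 in the mutant, and cpa5 at 6.19 ± 2.19 and 28.8 ± 10.7.

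Of 15 tested genes of xanthophores and of pteridine synthesis, the pathway that makes their yellow pigment, 6 fell in the mutant. gch2, which encodes a GTP cyclohydrolase that starts pteridine synthesis, fell from 105 ± 5.6 to 13.2 ± 2.9 FPKM (log2 fold change -2.92, SE 0.14, adjusted p = 6.63e-05). aox5, an aldehyde oxidase gene used as a xanthophore marker, fell from 8.78 ± 0.72 to 0.688 ± 0.14 FPKM (-2.53, SE 0.13). The transporter gene slc2a11b fell from 13.6 ± 2.1 to 2.39 ± 0.77 FPKM (-2.12, SE 0.19), and its relative slc2a15a from 10.8 ± 1.1 to 3.84 ± 0.83 (-1.30, SE 0.15). The other members that fell were paics and slc2a15b, 0 rose and 9 did not pass, and 6 fell when adjusted over the list alone. The list's median log2 fold change was -0.40, with a camera adjusted p of 1.56e-07. That call was lost with an estimated correlation (adjusted p = 0.27), while fry, which asks whether the members move one way on balance, gave an adjusted p of 0.00342.

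Of 16 tested members of the purine synthesis list, which shares paics, gart and atic with the xanthophore list, 4 fell in the mutant. paics fell from 56.8 ± 4.0 to 38.3 ± 1.9 FPKM (-0.56, SE 0.08), gmps, the GMP synthetase gene, from 19.4 ± 0.35 to 13.8 ± 0.58 (-0.47, SE 0.07), and pfas from 6.87 ± 0.98 to 4.06 ± 0.32 (-0.63, SE 0.13). prps1a was also called lower, at 38 ± 1.5 and 27.1 ± 2.7 FPKM. 0 rose, and 4 fell when adjusted over the list alone (median -0.16, camera adjusted p = 0.000631). With an estimated correlation, here -0.039 and so below the preset 0.01, the adjusted p was 0.27. The number of members called lower was 0 without wild-type replicate 1 or 3 or mutant replicate 1 or 2, and 1 without wild-type replicate 2. Other pigment cell lists did not pass: the melanophore list had 0 called members of 12 (camera adjusted p = 0.252), and the iridophore list had 1 of 13, gmps, called lower (adjusted p = 0.457). Without wild-type replicate 1 the melanophore adjusted p was 0.0496, and 0 iridophore members were called without any 1 of wild-type replicates 1, 2 and 3 or mutant replicates 1 and 2.

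Of 17 tested macrophage and microglia genes, 3 fell in the mutant. ccl34b.1, a chemokine gene, fell from 11.6 ± 2.3 to 1.73 ± 0.040 FPKM (log2 fold change -2.20, SE 0.14, adjusted p = 0.000311). lgals3bpb, a galectin-binding protein gene, fell from 5.56 ± 1.39 to 1.65 ± 0.75 FPKM (-1.33, SE 0.24), and spi1a, a myeloid transcription factor gene, from 1.64 ± 0.23 FPKM to 0.489 in mutant replicate 1, with no listing in the other mutant libraries (-1.21, SE 0.23). Of the others, 0 rose and 14 did not pass, with 5 lower when adjusted over the list alone. The median log2 fold change was -0.12 and the mean -0.45, with a camera adjusted p of 0.0031. The median was -0.18 without wild-type replicate 3 and without mutant replicate 1, and -0.21 with first-exon events alone. The call was lost with an estimated correlation (adjusted p = 0.276), and also with a filter of 5 FPKM (adjusted p = 0.127) and with last-exon events alone (adjusted p = 0.0931). The number of members called lower was 1 without any 1 of wild-type replicates 1, 2 and 3 or mutant replicate 2, and 2 without mutant replicate 3. mpeg1.1, the usual macrophage marker, has no first-exon or last-exon event in the tables per library, and so no direction here, as is true of lgals9l1 and mafba. The authors' deposited table gave their adjusted p as 0.000466, 0.00129 and 0.0118. The neutrophil list had 0 called members of 9 (camera adjusted p = 0.57) and the osteoclast list 0 of 8 (adjusted p = 0.635).

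Of 10 tested exocrine pancreas genes, 5 rose in the mutant. cel.1, a carboxyl ester lipase gene, rose from 0.937 ± 0.40 to 7.05 ± 2.5 FPKM (log2 fold change 2.02, SE 0.28, adjusted p = 0.0136), cpa4 from 3.13 ± 0.75 to 11.6 ± 3.4 (1.58, SE 0.23), and cpa5 from 6.19 ± 2.19 to 28.8 ± 10.7 (2.01, SE 0.33). The elastase gene ela3l rose to 6.69 ± 3.3 FPKM from 0.881 and 0.604 in wild-type replicates 1 and 3, with no listing in wild-type replicate 2 (2.29, SE 0.40). The fifth was ctrl, 0 fell and 5 did not pass, and 8 were higher when adjusted over the list alone (median 1.65, camera adjusted p = 1.11e-08). With an estimated correlation the adjusted p was 0.72. The list mean per library, in log2(FPKM + 1), was 1.98, 2.0 and 2.71 in wild type and 4.35, 4.12 and 3.13 in mutant replicates 1, 2 and 3, so that mutant replicate 3 and wild-type replicate 3 lay nearest each other. The number of members called higher was 1, 0 and 3 without wild-type replicates 1, 2 and 3, and 1, 0 and 8 without mutant replicates 1, 2 and 3. prss59.1 and cpb1, genes of a trypsin and a carboxypeptidase, and sycn.2 had no total here. Their adjusted p in the authors' deposited table was 0.000466 for both enzymes and 0.0548 for sycn.2, without a direction.

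**Figure D2:**
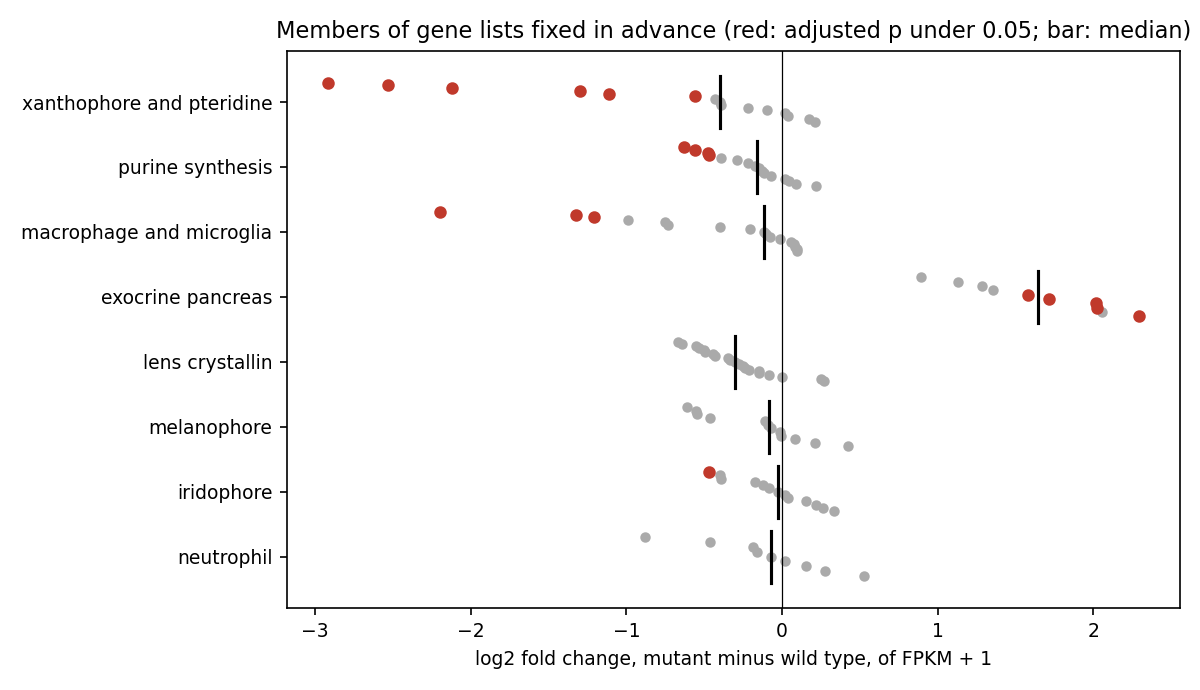
Log2 fold changes (mutant minus wild type, horizontal axis) of the tested members of 8 gene lists, with members at an adjusted p under 0.05 in red and each list's median as a black bar. The xanthophore median lies at -0.40 and the exocrine pancreas median at 1.65.

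Among metabolic genes, fbp1a, which encodes a fructose bisphosphatase of gluconeogenesis, rose from 9.93 ± 0.24 to 15.9 ± 0.20 FPKM (log2 fold change 0.63, SE 0.08), and pygl, the liver glycogen phosphorylase gene, from 17.2 ± 2.3 to 28.0 ± 3.5 (0.67, SE 0.13). These were 2 of 20 tested members of the gluconeogenesis and glycogen list (median 0.22, camera adjusted p = 0.00297, and adjusted p = 0.72 with an estimated correlation). The number called was 1 without any 1 of wild-type replicates 1, 2 and 3 or mutant replicates 1 and 2, and 4 without mutant replicate 3. In the oxidative phosphorylation list 4 of 88 members rose, among them ndufv1 (106 ± 1.1 to 142 ± 6.3 FPKM) and ndufa4 (39.3 ± 3.7 to 66.6 ± 10.4), and 1 fell, ndufa5 (log2 fold change -2.28). That list had a median of 0.08 and a camera adjusted p of 0.0056, against an adjusted p of 0.72 with an estimated correlation. The number called higher was 0 without wild-type replicate 1 or 2 or mutant replicate 1 or 2, and 1 without wild-type replicate 3, and the list was not called without wild-type replicate 1 (median 0.042, adjusted p = 0.303) or mutant replicate 1 (0.05, adjusted p = 0.159). Its mean in mutant replicate 3 was 5.84, within the wild-type range of 5.77 to 5.94. mdh1ab, a cytosolic malate dehydrogenase gene, rose from 7.24 ± 0.38 to 22.5 ± 3.2 FPKM (1.5, SE 0.11) in a tricarboxylic acid cycle list that did not pass (camera adjusted p = 0.0716, and under 0.05 without wild-type replicate 3 or mutant replicate 3, with quantile normalisation and with first-exon events alone, at 0.0458, 0.0097, 0.0258 and 0.0419). The glycolysis list (0 of 32 members called, median 0.12, camera adjusted p = 0.0264) and the fatty acid synthesis list (0 of 22, median 0.20, adjusted p = 0.0369) were called higher, as were the liver list (0 of 21, median 0.15, adjusted p = 0.0108), the phototransduction list (0 of 29, median 0.33, adjusted p = 0.0136) and the circadian clock list (1 of 31, per1b, median 0.09, adjusted p = 0.0136). Each of these 5 had an adjusted p of 0.72 with an estimated correlation. These calls were lost in several settings. The phototransduction call was lost without wild-type replicate 1 or 2 or mutant replicate 1 or 2 (adjusted p 0.104 to 0.262), where the median was 0.17 without mutant replicate 1 and 0.19 without mutant replicate 2, and without mutant replicate 3 the median was 0.63 with 9 members called higher. The glycolysis call was lost without wild-type replicate 1 or mutant replicate 1 or 2 (0.12 to 0.295) and without trend and robust options (0.0626), and its median was 0.060 without mutant replicate 1 and 0.21 without mutant replicate 3. The fatty acid synthesis call was lost without wild-type replicate 2 or 3 or mutant replicate 1 or 2 (0.0761 to 0.101), with a filter of 5 FPKM (0.11) and with first-exon or last-exon events alone (0.0573 and 0.334). Its median was 0.089 with last-exon events alone. The liver call was lost without wild-type replicate 2 (median 0.068, adjusted p = 0.233) or mutant replicate 1 (median 0.033, adjusted p = 0.159) and with a filter of 5 FPKM (0.0593). The liver median was 0.25 without wild-type replicate 3 and 0.24 without mutant replicate 3, where 4 members were called higher. The circadian clock call was lost without wild-type replicate 2 (0.0791) and with last-exon events alone (0.0931). Mutant replicate 3 had a list mean of 4.24 for phototransduction, against 5.06 and 5.05 in the other mutant libraries, and so below the wild-type range of 4.38 to 4.73. Its mean was 4.96 for liver, against 5.44 and 5.31 in the other mutant libraries, and 5.53 for glycolysis, within the wild-type ranges of 4.80 to 5.08 and 5.52 to 5.61.

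In the fast muscle list acta1b, an actin gene, fell from 770 ± 65 to 524 ± 29 FPKM (log2 fold change -0.55, SE 0.08), and atp2a1, the calcium pump gene of fast fibres, by 0.35 on the log2 scale. The third member called lower, tnnt3b (-2.90), rests on first-exon events. The list had 3 called of 31 (median -0.11, camera adjusted p = 0.0141, and adjusted p = 0.72 with an estimated correlation). The list's call was lost under quantile normalisation (median -0.053, adjusted p = 0.244), without wild-type replicate 2 (0.0576) or 3 (0.084) and with last-exon events alone (0.115). Without wild-type replicate 2 or 3 or mutant replicate 1 or 2, 1 member was called lower. In the slow muscle list tnni1c, a troponin gene, rose from 18.3 ± 4.1 to 33.3 ± 0.96 FPKM, as 1 of 13 members, and the list did not pass (adjusted p = 0.118), except with first-exon events alone (median 0.19, adjusted p = 0.0419). No member was called higher without wild-type replicate 3 or mutant replicate 1, 2 or 3, and 1 was called lower without mutant replicate 3. The difference between the fast and slow lists was not tested. The neuromuscular junction list had 0 called members of 15 (adjusted p = 0.96). The lens crystallin list (0 of 21 members called, median -0.30, camera adjusted p = 5.00e-06), the cartilage and bone list (0 of 24, median -0.21, adjusted p = 0.00782) and the cell cycle list (0 of 37, median -0.09, adjusted p = 0.0308) were called lower, each with an adjusted p of 0.72 with an estimated correlation. The cell cycle call was lost without wild-type replicate 3 or mutant replicate 1 or 2 (adjusted p 0.178 to 0.356), with a median of -0.055 without mutant replicate 2, and the cartilage and bone call with last-exon events alone (0.0837). Leaving out 1 library brought the cartilage and bone median to -0.12 (without mutant replicate 3) and the lens crystallin median to -0.20 (without mutant replicate 1).

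Across the 43 lists tested, camera at its preset correlation called 15, of which 7 were lower and 8 higher. With an estimated correlation it called 0 (smallest adjusted p = 0.27), and fry called 3, the xanthophore, purine synthesis and macrophage lists. Splits of the 6 libraries that mix the genotypes also called up to 15 lists, so the preset-correlation calls alone do not set the genotypes apart. limma on the mean of each list per library, a test chosen after seeing the data, called 3 lists, the xanthophore (-0.78, adjusted p = 7.89e-05), macrophage (-0.45, adjusted p = 0.00157) and exocrine pancreas lists (1.63, adjusted p = 0.0179). Their SEs were 0.059, 0.058 and 0.33. limma draws each list's variance toward that of the other lists. The exocrine pancreas call thus rests in part on their smaller spread, and not only on its own spread between libraries.

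Among the genes with the greatest fold changes, some were listed in the event tables of 1 genotype only. The event tables can leave out a gene whose reads went to another transcript structure, so a missing listing does not mean that the gene was silent. trap1, a mitochondrial chaperone gene, stood at 13.4 ± 0.27 FPKM in wild type and was not listed in any mutant library. lrp12 was listed in the mutant libraries alone, at 11.3 ± 0.21 FPKM. The mutant level of trap1 and the wild-type level of lrp12 are thus not known here, and whether the expression of either gene changed is uncertain. Of the 24 genes that the naming rule took for their fold, 8 were listed in 1 genotype only, and for 10 only first-exon or only last-exon events passed the filter. Called in the same direction from first-exon events alone and from last-exon events alone were 13 of the 24. On the lower side these were gch2, aox5, slc2a11b, ccl34b.1, slc22a7a, vasnb and ndufa5, and on the higher side cel.1, cpa5, ela3l, agr1, znf770 and slc35g2a. Both kinds of event draw on the same transcript estimates, so they are not independent measures. For gch2, slc22a7a, vasnb, ndufa5, cpa5, znf770 and slc35g2a both gave the same fold change, and the shared direction adds nothing. Of the 24, 18 had a significant transcript, of unknown direction, in the authors' deposited table, and chmp1a, mynn, slc35g2a, ca15a, zranb1a and vasnb did not. The remaining genes of the rule were pycr1b, on the lower side, and those given above. Over all calls, 58 of 376 were listed in 1 genotype only, and 293 were listed in all 6 libraries. The calls outside those 293 rest in part on values entered as 0.

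The calls were set against the authors' deposited table, which was made from the same libraries and is not independent. Of the 376 called genes, 291 (77.4%) had at least 1 transcript at an adjusted p under 0.05 there, 70 had none and 15 were not tested. Of the 14825 genes tested there and not called here, 4605 (31.1%) had such a transcript. The authors' deposited table called 5953 transcripts of 5663 genes. Directions were not compared. The number of called genes with such a transcript was 108, 103 and 113 without wild-type replicates 1, 2 and 3, and 109 and 98 without mutant replicates 1 and 2.

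On chromosome 14, the 148 tested genes within 10 Mb of csf1ra that all 6 libraries listed included 5 called genes (3.38%), against 288 of 14868 (1.94%) elsewhere, a difference that did not pass a one-sided Fisher exact test (p = 0.164). bscl2l (chromosome 14, 5852328 to 5869113) was the most changed of them, at 8.38 FPKM in wild type and 1.35 in the mutant (log2 fold change -2.02, SE 0.18). gpc2, kazald2 and si:dkeyp-44a8.2 were also lower, and sh3bgrl was higher.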

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

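The tests on exon skipping, on genes without event totals and on genes listed in 1 genotype only were chosen after the main result was seen. Exon inclusion had not been used in the comparisons. The 2111 skipped exons tested had at least 1 FPKM in every library over the including and skipping forms together. limma on the logit scale called 6, of which 5 had higher inclusion in the mutant and 1 lower. An unadjusted limma p under 0.05 was found for 125 (5.92%), where chance gives 5%. The exon of fam21c on chromosome 13 (17968931 to 17969026, GRCz10) was included at 2.90% ± 1.5 in wild type and 98.2% ± 0.075 in the mutant (SD, n = 3, limma adjusted p = 0.00332). An exon of sfswap, a splicing regulator gene, on chromosome 21 was at 73.3% ± 5.7 and 99.3% ± 0.034. These shares come from transcript estimates and carry the same listing limits as the gene totals. A form not listed counted as 0, and 0.1 FPKM was added to each form. Where a form was not listed, the share follows this offset and the summed FPKM. A small SD is then no measure of precision. Whether this held for the exons named here was not examined.

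The authors' deposited table holds 2553 tested transcripts of 2038 genes with no first-exon or last-exon event, which the comparisons of gene totals did not use, and 500 of these transcripts were significant there. Of 149 such transcripts in the gene lists, 53 were significant, among them those of mpeg1.1, prss59.1 and cpb1.

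Of the called genes, 58 were listed in the event tables of 1 genotype only, 35 in the mutant and 23 in wild type. Of the 52 of these genes tested in the authors' deposited table, 35 (67.3%) had a significant transcript there and 17 did not. Such a transcript was found for 256 of 309 other called genes and for 31.1% of genes not called. Any transcript counted, without its direction, trap1 and lrp12 included, so these counts do not show that the genes' totals changed. Whether the event tables left out transcripts of the other genotype stays open for all 58.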

How the results depend on the processing

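First-exon events alone, last-exon events alone, genes listed in all 6 libraries and limma on list means were chosen after seeing the data. No named gene or list that was called turned direction. Medians of lists below the threshold crossed 0 in at least 1 setting for 13 of 43 lists. Among results named in the text, the medians of the melanophore list (0.013 without wild-type replicate 2) and the iridophore list (0.042 without wild-type replicate 1, 0.012 without mutant replicate 2) and the value of csf1b (-0.011 without wild-type replicate 2, -0.0077 without mutant replicate 1) crossed 0. Of all 376 calls, 5 had the opposite sign with first-exon events alone and 7 with last-exon events alone. csf1ra stayed called in each setting that gave a value (log2 fold change -4.48 to -2.03). The 376 called genes became 116 with the replicate block (53 higher and 63 lower), 236 among genes listed in all 6 libraries (115 and 121) and 159 with a log2 change of at least 1 (85 and 74). With a filter of 5 FPKM 125 genes were higher, and without trend and robust options 123 were lower. Leaving out 1 library gave 135 to 450 calls, 53 to 266 higher and 68 to 184 lower. Called genes with a significant transcript in the authors' deposited table, 291 at first, were 84 with the block, 192 among genes listed in all 6 libraries, 107 with a log2 change of at least 1, and 98 to 353 with 1 library left out. The 15 called lists became 0 with an estimated correlation, 3 with limma on list means and 9 to 21 with 1 library left out. With an estimated correlation the xanthophore list (median -0.40) and the macrophage list (-0.12) were no longer called. The macrophage list was also not called with a filter of 5 FPKM (-0.10) or last-exon events alone (-0.081). Fewer genes or libraries enter some of these settings. For the other losses the cause was not tested. The correlation estimated for the macrophage list (-0.016) lay below the preset 0.01, so more correlated members do not account for that loss. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.028, 0.0035 and 0.0062. Of the values of csf1rb, the ligand genes and the 24 genes named for their fold, 422 kept their side of the threshold, 40 lost it and 1 gained it. For the lists other than the xanthophore and macrophage lists, whose losses are given above, these counts were 697, 55 and 23. Library depth is unknown, so what it limits cannot be stated. Count models and term enrichment were not run.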

Other observations

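The tests of gene positions and of list means were chosen after the result was seen. Among the genes listed in all 6 libraries, chromosome 19 held more called genes than its share, with 31 of 606 (5.12%, one-sided Fisher exact adjusted p = 2.4e-05 over 25 chromosomes). It was followed by chromosome 25 with 23 of 471 (adjusted p = 0.000661) and chromosome 18 with 20 of 489 (adjusted p = 0.0127), by the same Fisher exact test. Between 5 and 10 Mb of chromosome 19, 12 of 83 genes were called, among them ndufv1, crabp2b, rab25a and slc2a3a. The Fisher exact test takes genes as independent, while called genes lay close together, as given below. The adjusted p of these chromosomes may thus be too small. On chromosome 25, 6 of 81 were called between 0 and 5 Mb, 5 of 60 between 5 and 10 Mb, and 5 of 86 between 15 and 20 Mb, the window of the carboxypeptidase genes cpa4 and cpa5.

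Called genes lay close together along chromosomes. Among the 293 called genes listed in all 6 libraries, 135 pairs lay within 1 Mb, against a mean of 75.1 and a maximum of 118 in 10000 random placements among 15016 genes (permutation p = 0.0001, the smallest these placements can give), which argues against random placement. Only 5 called genes lay within 10 Mb of csf1ra, so leaving out that window could remove few pairs. It left 132, and this test adds nothing to the count of 5. Linkage within that window leaves these 132 pairs unexplained. Taking as many genes of smallest p from each of the other 9 splits of the libraries gave at most 92 pairs, fewer than 135. That 92 lies between the mean and the maximum of the random placements. These splits called at most 4 genes, so the genes taken from them were mostly not called ones. Whether neighbouring genes vary together between any libraries thus cannot be decided by these splits. Sequence differences between the fish stocks in other regions may be a candidate explanation, as may regulation shared by neighbours, and neither was tested.

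By camera at its preset correlation the exocrine pancreas list was higher and the lens crystallin list lower in the mutant, which was lost for both with an estimated correlation (adjusted p = 0.72). The lowest mutant library lay 0.42 above the highest wild-type library in the exocrine pancreas mean (log2). In all 376 called genes, which include 5 of the 10 members of this list, the genotypes did not overlap. The gap in the mean was thus nearly fixed by the calls. It cannot decide whether 1 mutant library is the whole cause. The lens crystallin mean was -0.29 in the mutant relative to wild type (log2, SE 0.11), where a uniformly later stage could raise both lists. This is more than 2 SE below 0, opposite to what such a stage difference could give, but limma on list means gave an adjusted p of 0.138. Of 21 members 19 were lower, but they varied together (estimated correlation 0.71), so they are not separate evidence. A condition that the genotypes' libraries not overlap, added after the value was seen, was not met (6.37 in wild-type replicate 1, 6.38 in mutant replicate 2), so a uniform difference in stage cannot be told apart from the genotype by this list. Other called lists were phototransduction (24 of 29 members higher), liver (16 of 21 higher) and cell cycle (30 of 37 lower), directions that a later stage could also give. The cartilage and bone list was lower (16 of 24 members). These lists were not weighed here, and whether a difference in stage moved them was not tested.

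Of the 10 ways to split the 6 libraries into 3 and 3, 1 gave as many called genes as the genotypes, the real split itself with 376, and the highest other gave 4. For the called lists the real split gave 15 and the highest other also 15, so that 2 splits gave as many. With 10 splits no share under 0.05 can be reached.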
